A study of Arabidopsis thaliana with 3 samples.

How the data were processed

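Immunoprecipitates from flowers of 3 Arabidopsis lines were made into small RNA libraries by the submitters, with 1 library per group (vector control, AGO1-DDH and AGO1-DAH). Per the labels' protocols, a cloning linker and a 5′ RNA adapter were ligated, the cDNA was amplified by PCR and bands in the size range of small RNAs were cut from a gel. The protocol names no molecular identifiers, so reads are not independent molecules. Per the submitters' processing notes, reads were placed on the TAIR10 genome with Bowtie 0.12.8. Mismatch and multiple-hit settings and the treatment of unplaced reads are not given in the sources used here.

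The deposited values are whole-number counts, 1 per distinct read sequence, repeated by the authors on a line for each genomic position of that sequence. Positions cover the nuclear chromosomes 1 to 5, per the file headers. Read sequences run from 18 to 36 nt. The deposited files were checked against the reference. Every line matched the plus strand of the genome exactly, which showed that a minus-strand read is written as its reverse complement, and such sequences were turned back here. For 2000 sampled sequences per library, all exact positions in the nuclear genome were listed. The source field names the DDH library in each of the 3 files, so the sample of a file was taken from its recorded assignment and not from that field. Each library's depth is the sum of its counts over distinct sequences, 20443343 for vector, 20609290 for DDH and 20615806 for DAH, which is the number of reads placed on the nuclear chromosomes.

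All further values were computed here. The annotation was that of RefSeq for the same TAIR10 chromosomes, with 37899 genes and pseudogenes and 428 mature miRNA records. A read with several positions was shared equally among them. Each position was assigned by its midpoint to the first class that held it. The order was ribosomal RNA, transfer RNA, small nuclear or nucleolar RNA, miRNA precursor, TAS locus, gene, pseudogene, organelle match, masked repeat and no annotation. The large ribosomal subunit RNA lacks a record of its own, so the ribosomal class was extended by 4000 nt downstream of the 5.8S records. A transposon annotation was not used here, and pseudogene records and soft-masked sequence stood in for it. Organelle genomes were not used for placement, and an organelle match is a nuclear-placed read that also occurs there.

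Of 77 listed miRNA members, 75 matched an annotated mature miRNA exactly and made up 59 families. The other 2 (miR824 and miR867) were left out of the families. A guide read had both ends within 2 nt of the annotated ends. Star positions came from annotated precursors, clipped to at most 200 nt on either side of the guide and folded by RNAfold (ViennaRNA 2.7.2), with overhangs of 2 nt. A star was found at 114 of 119 loci, and 56 of the 58 with an annotated opposite arm lay within 2 nt of it. Genes were measured by their 21-nt reads without reads that occur in a miRNA precursor. Gene lists were 8 TAS loci, 35 genes known to give secondary siRNAs (18 PPR genes and 17 others) and 41 target genes not known to. These targets are called miRNA target genes below, although ARF2, ETT and ARF4 among them are of a class regulated by a TAS3 siRNA. A gene needed 50 reads over DDH and DAH, a family 100 over the libraries compared, and a star share 500 reads in each library.

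For the register, the trigger's site in a TAS transcript was found by pairing score (a mismatch cost 1, a G:U pair 0.5), and the cut was set opposite guide position 10. Among TAS3 sites within 3 of the best score, the site nearest the 3′ end was used. A 21-nt read was in register when its start lay a multiple of 21 nt from the cut, with the 2-nt overhang of the other strand allowed for. The reads at TAS loci here include those that also occur in a miRNA precursor.

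With 1 library per group no test between conditions was possible and no p-value was computed. Shares carry Wilson intervals, levels exact Poisson intervals and ratios exact conditional binomial intervals, all at 95% and for counting error only. A count of 0 was given a floor of 3 counts. A list's median log2 ratio carries an order-statistic interval and a percentile among 10000 random lists, in which each member was replaced by one of the 50 other genes nearest in mean abundance. That percentile describes these libraries only. The steps were tested on simulated data. In a simulation of the DAH over DDH gene comparison with 1560 genes, 200 of them changed, median log2 ratios of -2.93, -1.96, -0.99 and 1.02 were recovered for -3, -2, -1 and 1. The intervals covered the simulated value in 94% to 100% of genes, by fold. The gene counts were Poisson draws, with no amplification and no reads shared between genes, so the simulation checks the computation and not those sources of error. Of 200 unchanged lists, 4.5% fell under percentile 5. A simulated register share of 60% came back as 60.4%.

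The groups, comparisons, gene lists, alternatives and the rule for named items were fixed before the data were examined. That rule took the 12 most abundant families, the 5 highest and 5 lowest DAH over DDH ratios among families with at least 1000 reads, and the 3 highest and 3 lowest DDH over vector ratios among families with at least 100. It added 11 control families, the 8 TAS loci, the 6 secondary siRNA genes with most reads (AGO1 among them), and the 4 largest differences in star share in each direction. The alternatives changed the scaling, the treatment of reads with several positions, the read lengths, the guide and star definitions, the minimum reads and the counting of each distinct sequence once. A scaling without miR159, a scaling to the median of other genes, leaving out the 3 most abundant sequences and another TAS3 site were added after seeing the data. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, biopython 1.88 and matplotlib 3.10.9.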

Results

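Small RNA was sequenced from immunoprecipitates of Argonaute 1 (AGO1), the protein that carries most plant microRNAs (miRNAs) and can cut the transcripts they pair with. The material was Arabidopsis thaliana flowers of stages 1 to 12 in the Columbia background. One line carried an HA epitope-tagged wild-type AGO1, called DDH after the catalytic residues of its slicer site. A second carried the same construct with the middle residue changed, called DAH, and the last carried a vector with GUS as the control for what the immunoprecipitation holds without tagged AGO1. Each group had 1 library, so no spread between replicates could be measured and every comparison is of these libraries, not of the genotypes. The vector library held 20443343 reads, the DDH library 20609290 and the DAH library 20615806. Intervals are 95% intervals for counting error only, since reads amplified without molecular identifiers are not independent molecules. Levels are given as RPM, reads scaled to 1000000 reads in the library, and positions are on the TAIR10 chromosomes. An RPM value is a share of its own library, so a level under that of the vector library does not show an amount below background.

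The DDH library held 1032345 distinct sequences at full depth, the DAH library 774478 and the vector library 202741. Thinned to 1000000 reads each, the expected numbers were 117233 in DDH, 78800 in DAH and 77383 in the vector library. A single sequence, the miR159a guide TTTGGATTGAAGGGAGCTCTA of MIR159a (AT1G73687, chromosome 1, 27713234 to 27713254, minus strand), made up 62.0% of the vector reads. It made up 29.6% of the DDH reads and 43.3% of the DAH reads. A mean of 101 reads stood behind each distinct vector sequence, against 20.0 in DDH and 26.6 in DAH.

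AGO1 is known to hold mostly small RNAs of 21 nt that begin with U, and the length and first-base comparison asked whether both forms of the protein held that kind. Reads of 21 nt made up 65.6% of the DDH library and 72.6% of the DAH library, and 77.3% of the vector library. Reads of 20 nt were 12.3% in DDH and 11.7% in DAH against 2.42% in the vector library. Of these 20-nt reads, miR319 gave 46.5% in DDH and 63.2% in DAH. Reads of 24 nt were 10.2% in DDH and 4.78% in DAH, with 11.9% in the vector library. Reads of 25 to 36 nt, a length range of RNA fragments, were 1.97% of the vector library, 0.154% of DDH and 0.0764% of DAH. The Wilson interval of the DDH 21-nt share, the widest of these, ran from 65.63% to 65.67%.

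**Figure D1:**
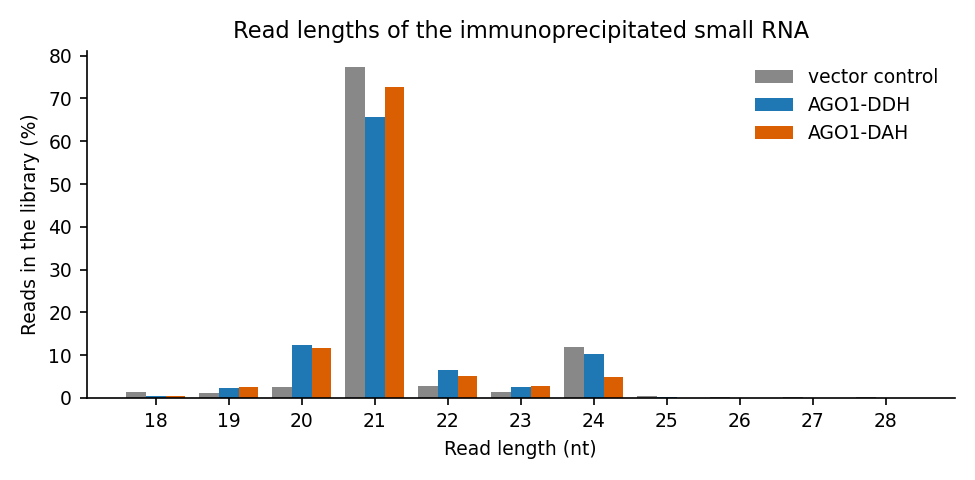
Share of reads (percent, vertical axis) by read length (nt, horizontal axis) in the vector, AGO1-DDH and AGO1-DAH libraries, 1 library each. The 21-nt bar is the tallest in every library, at 77.3%, 65.6% and 72.6%, and the 24-nt bar of DAH (4.78%) lies below that of DDH (10.2%).

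A 5′ U began 84.2% of DDH reads, 89.5% of DAH reads and 85.1% of vector reads. Without miRNA reads the shares were 87.3%, 82.5% and 35.5% in the same order. With each distinct sequence counted once they were 80.4%, 76.4% and 40.3%. In both settings DDH lay above DAH and the vector library far below them. The 24-nt reads set the AGO1 libraries apart from the control by their first base. In the vector library 59.4% of them began with A, the base preferred by the AGO4 group, and 24.9% with U. In DDH 96.96% began with U and 1.87% with A, and in DAH 85.9% began with U and 8.25% with A. In RPM, 24-nt reads with a 5′ A stood at 2.70% of their vector level in DDH and at 5.60% in DAH. A 5′ C began 12.8% of DDH reads and 8.44% of DAH reads, and miR319 gave 87.6% and 85.4% of those. Its C-starting form CTTGGACTGAAGGGAGCTCCC (MIR319b, chromosome 5, 16660470 to 16660490, minus strand) had 2291955 reads in DDH and 1437739 in DAH. The 21-nt reads with a 5′ A, the AGO2-like class, were 4.02-fold lower in DAH than in DDH, at 3270 against 13149 RPM, with 4560 RPM in the vector library.

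Sorted by annotation, miRNA precursors gave most reads in every library, with 74.2% in DDH, 85.3% in DAH and 78.0% in the vector control. Trans-acting siRNA (TAS) loci gave 1.45% of DDH reads, 0.910% of DAH reads and 0.384% of vector reads. Fragments of structural RNAs marked the control. Ribosomal RNA was 3.61% of the vector library, 6.22-fold above DDH and 16.2-fold above DAH, and transfer RNA was 53.4-fold and 78.5-fold above them. Small nuclear and nucleolar RNA was 0.250% of the vector library, 0.0240% of DDH and 0.0138% of DAH. Protein-coding and other genes gave 4.39% of vector reads, 5.96% of DDH reads and 3.46% of DAH reads. Pseudogenes gave 2.10%, 3.32% and 1.65% in the same order, and masked repeats 1.23%, 2.16% and 1.40%. Reads that also match an organelle genome and fell in no class before it were 0.0287%, 0.0181% and 0.0111%. Sequence with no annotation gave 9.49% of vector, 12.3% of DDH and 6.997% of DAH reads.

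The comparison with the vector library asked which miRNA families the tagged proteins held above background. Of 47 families with at least 100 reads over the DDH and vector libraries, 35 were over 2-fold higher in DDH and 5 over 2-fold lower, with a median log2 ratio of 2.21 (order-statistic interval 1.51 to 2.88). For DAH, 32 of 46 families were over 2-fold higher than in the vector library and 4 lower, with a median of 2.15 (1.43 to 2.71). The 59 families together held 70.6% of DDH reads, 83.2% of DAH reads and 76.7% of vector reads. Outside miR159, which targets MYB transcription factors, they held 36.1%, 34.2% and 8.12%. Dividing each library by the median family ratio, which puts that median near 0 by construction, gave medians of -0.15 and -0.07.

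The families furthest above the control in DDH were miR393, miR827 and miR169. For miR393, which targets the auxin receptors TIR1 and the AFB proteins, the level was 396.9 RPM in DDH, 155 in DAH and 2.40 in the vector library, 165.6-fold higher in DDH. For miR827, a phosphate-starvation miRNA, DDH stood 103-fold above the vector library, and for miR169, which targets NF-YA transcription factors, 95.6-fold, on 5 and 6 vector reads. miR860 had 7.62 RPM in DDH and no reads in the vector library, 51.9-fold above a floor of 3 counts with a counting lower limit of 41.7. It was counted among the 47 at that floor. The 24-nt miR163 (MIR163, AT1G66725, chromosome 1, 24884359 to 24884382, plus strand) stood 49.3-fold above the vector in DDH and 15.2-fold in DAH. The leaf-polarity miRNA miR165 was 5.12-fold higher in DDH and 5.02-fold in DAH, and miR166 3.27-fold and 3.57-fold. The direction for miR166 flipped to log2 -0.65 and -0.38 under the median of family ratios. miR319, which targets TCP genes, was 11.01-fold and 10.1-fold higher, miR396, which targets GRF genes, 5.06-fold and 4.67-fold, and miR172, which targets AP2, 16.0-fold and 26.5-fold. The log2 ratio of miR396 in DDH was -0.02 under the median of family ratios.

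Some families were lower in the DDH library than in the vector library, or close to it. miR773 was at 3.35 RPM in DDH and 20.4 in the vector library, a log2 ratio of -2.61 that does not hold for its exact annotated guide, with 8 reads in DDH and 0 in the vector library. miR447 stood at -1.62, but its exact guide had 444 reads in each of these libraries. miR825 stood at -1.39. In contrast, miR447a.2-3p, another miRNA of the MIR447 precursors and not counted in that family, was 4.58-fold higher in DDH than in the vector library. miR159 was 1.99-fold lower in DDH than in the vector library, with 344741 against 685626 RPM, and it was at 489478 RPM in DAH. miR156, which targets SPL genes, was at log2 -1.21 in DDH and -1.56 in DAH. miR161, which targets PPR genes, stood slightly above the vector library, at 36377 RPM in DDH, 37681 in DAH and 35487 in the control, and scaling turned its direction against the vector, with log2 ratios from -2.32 to 0.15 in DDH and from -2.13 to 0.09 in DAH. miR168, which targets AGO1 itself, was at 4943 RPM in DDH and 5298 in the vector library, with log2 ratios from -2.46 to 0.02 over the scalings. In DAH it stood 4.63-fold above the vector library, a direction that flipped to log2 -0.0043 under the median of family ratios.

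The comparison between the tagged proteins asked whether AGO1 without slicer activity held the same miRNAs. Most families were close. Of 49 families with at least 100 reads over both libraries, 32 lay within 2-fold, 12 were over 2-fold lower in DAH and 5 over 2-fold higher. The median log2 ratio was -0.12 (-0.55 to 0.13). With levels scaled to reads outside miR159 it was 0.24, and the balance turned, with 9 families over 2-fold higher in DAH and 7 lower. For 45 of the 49 the counting interval excluded a ratio of 1. Several of the most abundant families lay near 1. The DAH over DDH ratio was 0.979 (0.976 to 0.982) for miR165, 1.09 for miR166, 1.04 for miR161, 0.919 for miR319, 0.923 for miR396 and 0.792 for miR403, which targets AGO2. All these 6 directions, and those of miR156 and of miR173 (0.981), flipped over the scalings. With the exact guide alone miR319 turned as well, to a log2 ratio of 1.05. miR173, the trigger of TAS1 and TAS2, was at 33.4 RPM in DDH, 32.8 in DAH and 4.55 in the vector library.

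miR168 stood apart. It was at 24523 RPM in DAH against 4943 in DDH, 4.96-fold higher (4.93 to 5.00), and its log2 ratio lay between 2.07 and 2.67 over the scalings. Its 21-nt form TCGCTTGGTGCAGGTCGGGAA, shared by MIR168a (AT4G19395, chromosome 4, 10578652 to 10578672, plus strand) and MIR168b (AT5G45307, chromosome 5, 18358873 to 18358893, minus strand), had 67524 reads in DDH and 290143 in DAH. The 22-nt form TCGCTTGGTGCAGGTCGGGAAC had 12244 and 161864 reads. Reads of 22 nt made up 12.0% of the family in DDH, 32.0% in DAH and 9.37% in the vector library. Among families with at least 1000 reads over both libraries, the next highest ratios were those of miR395, which acts in sulfate assimilation, at 2.86 (2.78 to 2.93), and miR848 at 2.13 (1.89 to 2.39). miR164, which targets NAC genes such as CUC2, followed at 1.93 (1.80 to 2.07) and the phosphate-responsive miR399 at 1.85 (1.72 to 1.99). miR172 was 1.65-fold higher, at 308 against 187 RPM. miR159 was 1.42-fold higher.

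At the other end, miR390 was 5.04-fold lower in DAH, with 15.4 against 77.4 RPM and 33.6 in the vector library, so the DAH share lay below that of the control. This miRNA is known to act with AGO7, and its main guide AAGCTCAGGAGGGATAGCGCC begins with A. miR843 was 4.45-fold lower, with 13.4 against 59.8 RPM and 20.98 in the vector library. The copper-responsive miR408 was 3.68-fold lower (77.3 against 284 RPM), miR163 3.25-fold, miR827 3.09-fold and miR393 2.55-fold. miR158 was 2.53-fold lower (11020 against 27911 RPM), and miR167, which targets ARF6 and ARF8, was 1.95-fold lower (428 against 837 RPM). miR162, which targets DCL1, was 1.46-fold lower (274 against 401 RPM). With all guide forms counted, miR773, miR447 and miR825 were 3.45-fold, 1.26-fold and 1.80-fold higher in DAH than in DDH. The exact miR447 guide went the other way, with 444 reads in DDH and 361 in DAH, and the exact miR773 guide had 8 and 12. miR828, the trigger of TAS4, had 6 reads in DDH and 0 in the other libraries, where a count of 0 allows up to 3 reads. The counting interval of DAH over DDH ran from 0 to 0.849, and DDH stood 1.98-fold above a floor of 3 counts in the vector library, with a counting lower limit of 1.17, all on these 6 reads.

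**Figure D2:**
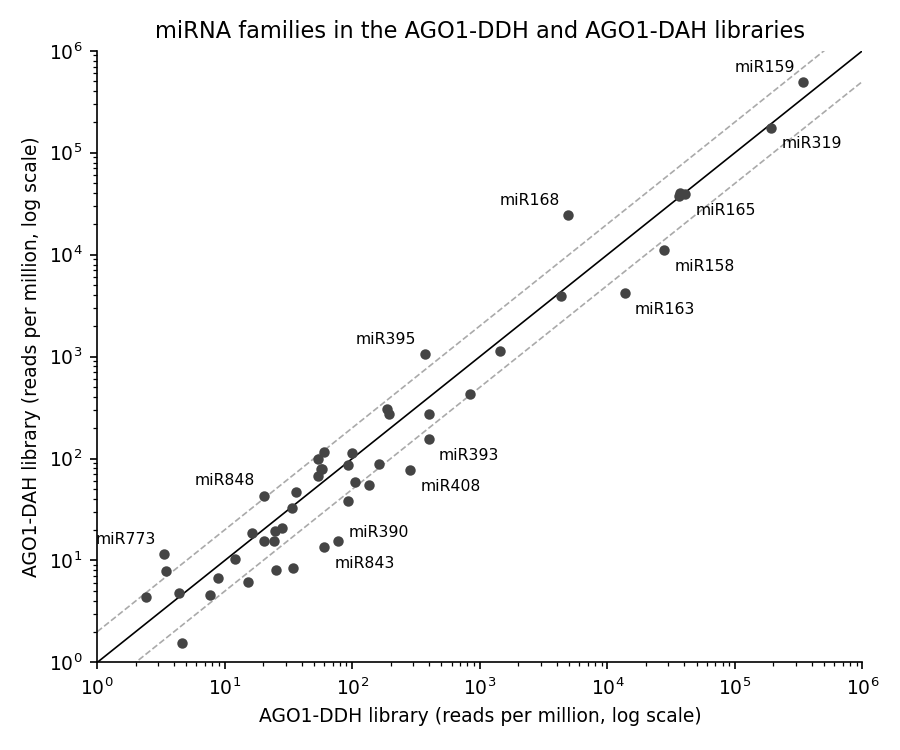
Each point is a miRNA family, with its RPM in the AGO1-DDH library (horizontal, log scale) and the AGO1-DAH library (vertical, log scale), 1 library each. The solid line marks equal levels and the dashed lines a 2-fold difference, and of the 49 families with at least 100 reads 32 lie between the dashed lines while miR168 lies 4.96-fold above the line and miR390 5.04-fold below it.

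An Argonaute loads a duplex and then discards the passenger, or star, strand, in some cases by cutting it, so the star share was compared between the slicer mutant and the wild type. In most families it was small in both. Of 30 families with a folded star and at least 500 guide and star reads in each library, 19 had a star share under 1% in both. The median difference was 0 percentage points (-0.0003 to 0.0673). The share was higher in DAH in 14 families and lower in 12, and the Wilson intervals lay apart in 7 and 3 of them. Counted as all precursor reads outside the guide, 22 of 33 families were higher.

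The largest differences went both ways. The star share of miR171, which targets HAM genes, was 46.0% (44.7 to 47.2) in DDH and 85.0% (84.4 to 85.6) in DAH, with 99.0% in the vector library. Its main star form TATTGGCCTGGTTCACTCAGA (MIR171a, chromosome 3, 19073452 to 19073472, plus strand) had 2786 reads in DDH, 10203 in DAH and 28344 in the vector library. That sequence also occurs in MIR170 (AT5G66045), so its reads cannot be given to MIR171a alone. The share for miR408 was 22.5% in DDH, 44.4% in DAH and 81.4% in the vector library. Its star reads were 1702 in DDH and 1274 in DAH, beside 5860 and 1593 guide reads. miR156 had 11.9% and 21.4%, and miR840 5.45% and 11.6%. For miR840 the star reads were 160 and 147, beside 2775 and 1123 guide reads. In the other direction stood miR164, with 22.4% in DDH and 7.86% in DAH, and miR472, which targets disease-resistance genes, with 48.7% and 39.1%. The next largest differences were small, 0.179% and 0% for miR399 and 1.07% and 0.921% for the ARF regulator miR160. For miR393, whose star is known from AGO2, the share was 1.69% in DDH, 4.01% in DAH and 69.8% in the vector library. Its star reads were 141 in DDH and 134 in DAH beside 8179 and 3204 guide reads, so the shares differ through the guide.

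TAS transcripts are cut under the guidance of a miRNA and then made into 21-nt siRNAs in steps from the cut, so they tell whether siRNAs that depend on slicing reached each protein. At all 7 TAS loci with at least 50 reads, 21-nt reads were lower in the DAH library. The ratio of DDH to DAH was 4.48 (4.33 to 4.64) at TAS1a, 2.48 at TAS1b, 1.42 at TAS1c, 2.18 at TAS2, 1.88 at TAS3a, 1.84 at TAS3b and 5.31 (4.61 to 6.16) at TAS3c. TAS2 was the most abundant, with 4694 RPM in DDH, 2151 in DAH and 1411 in the vector library. TAS4 had 4 reads in DDH, 2 in DAH and 0 in the vector library, a DDH to DAH ratio of 2.00 with a counting interval of 0.287 to 22.1. The median log2 ratio of the 7 loci, -1.13, stood at percentile 74.2 among 10000 random lists of genes matched on abundance, although 3 members lay outside the abundance range of the genes to match. The 1478 other genes with enough 21-nt reads had a median of -1.09, and with that median set to 0 the TAS median was -0.04.

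The loci cut by miR173 differed in the balance of their registers. These are TAS1a (AT2G27400, chromosome 2, 11721539 to 11722468), TAS1b (AT1G50055, chromosome 1, 18549204 to 18550042), TAS1c (AT2G39675, chromosome 2, 16537288 to 16538277) and TAS2 (AT2G39681, chromosome 2, 16539384 to 16540417), all noncoding RNA genes on the minus strand. The share of 21-nt reads in register with the miR173 cut was 85.8% (85.3 to 86.3) in DDH and 21.5% (20.3 to 22.8) in DAH at TAS1a. It was 41.6% and 18.6% at TAS1b, 48.5% and 15.9% at TAS1c, and 53.8% and 32.9% at TAS2, where an even spread over the 21 registers gives 4.76%. The vector library stood at 57.2%, 20.3%, 68.9% and 36.7%. In RPM, the in-register reads were 17.9-fold, 5.52-fold, 4.33-fold and 3.57-fold lower in DAH than in DDH. Reads out of register had DAH over DDH ratios of 1.24, 0.563, 1.15 and 0.665. The median difference in share was -27.8 percentage points over the 4 loci, and with each distinct sequence counted once it was -1.25.

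**Figure D3:**
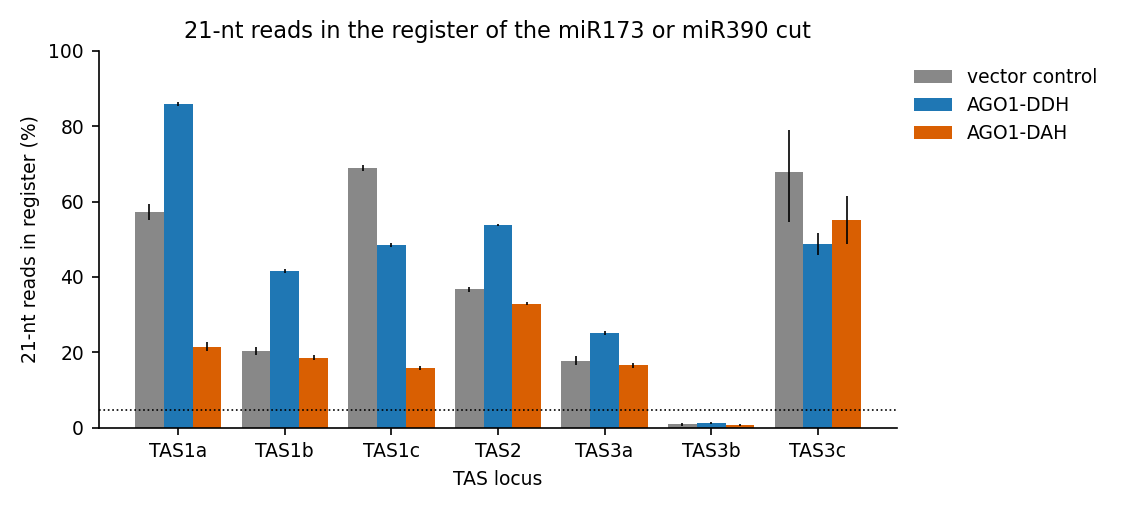
Share of 21-nt reads (percent, vertical axis) in the register set by the miR173 cut at TAS1 and TAS2 or the miR390 cut at TAS3, by locus, in 1 library per group with Wilson 95% intervals as error bars. The dotted line is the 4.76% of an even spread, and at TAS1a, TAS1b, TAS1c and TAS2 the DAH bars (21.5%, 18.6%, 15.9% and 32.9%) lie below the DDH bars (85.8%, 41.6%, 48.5% and 53.8%).

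The most abundant siRNAs of these loci differed in size and direction. TTCTAAGTCCAACATAGCGTA, encoded by TAS1a, TAS1b and TAS1c (at TAS1b chromosome 1, 18549544 to 18549564, minus strand), had 11441 reads in DDH, 97 in DAH and 329 in the vector library. ATTCCGGACATCTCCCATTTT of TAS1b (chromosome 1, 18549483 to 18549503, plus strand) had 5555 reads in DDH and 1 in DAH. TTTGAACTTGTGTATTTTGAA of TAS2 (chromosome 2, 16539938 to 16539958, minus strand) had 43013 and 12709. TTATGATTGATAGGATGGTAG of TAS1b (chromosome 1, 18549593 to 18549613, minus strand) had 3855 and 2330, a smaller difference than that of its locus. In contrast, the 22-nt TAACTCTTGTTGATCGGATGGT of TAS2 (chromosome 2, 16539817 to 16539838, minus strand) had 27488 reads in DDH and 42843 in DAH, and TGTTGATCGGATGGTAGAAAC of TAS2 (chromosome 2, 16539811 to 16539831, minus strand) had 2828 and 6167. These sequences were chosen from the most abundant of each locus after their values were seen.

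At the TAS3 loci, which are cut by miR390 with AGO7, the register shares of DDH and DAH were 25.2% and 16.6% at TAS3a (AT3G17185, chromosome 3, 5861491 to 5862437), 1.25% and 0.825% at TAS3b (AT5G49615, chromosome 5, 20134200 to 20134786) and 48.8% and 55.2% at TAS3c (AT5G57735, chromosome 5, 23394005 to 23394500). At TAS3a the intervals (24.6 to 25.8 and 15.9 to 17.3) lay apart, and in-register reads were 2.86-fold lower in DAH. The register 1 nt before it held 21.9% in DDH and 29.1% in DAH. The TAS3a site used had a pairing score of 5. The register of the best-scoring site, with a score of 3, held 19.3% in DDH, 14.1% in DAH and 19.3% in the vector library. The intervals of TAS3b (1.04 to 1.51 and 0.602 to 1.13) and of TAS3c (46.0 to 51.6 and 48.7 to 61.6) overlapped. At TAS3b the shares lay under the 4.76% of an even spread, so the register there did not follow the site used. The tasiARF form TTCTTGACCTTGTAAGACCCC of TAS3a (chromosome 3, 5862206 to 5862226, plus strand), a regulator of auxin response factors, had 2373 reads in DDH and 2770 in DAH. The form shifted by 1 nt, TCTTGACCTTGTAAGACCCCA, had 2176 and 808, and TTTTCTTGACCTTGTAAGACC, shared by TAS3a and TAS3b, had 2910 and 2697.

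A further list held 35 genes known to give secondary siRNAs when a 22-nt miRNA or tasiRNA targets them, and 23 had enough 21-nt reads. All 23 were over 2-fold lower in DAH, with a median log2 ratio of -2.47 (-2.94 to -1.83). None of the 10000 matched random lists had a median as low, the lowest being -2.01. Most of this came from genes for pentatricopeptide repeat (PPR) proteins, which act on organelle RNA. All 16 measured PPR genes were lower, 15 of them over 4-fold, with a median of -2.89 (-3.40 to -2.39), again below every matched list. PPR genes share reads, so their values are not independent, while the interval and the matched lists treat genes as independent. Among the 1478 other genes 96.3% were lower and 9.27% over 4-fold lower, and with their median set to 0 the PPR median was -1.81 and the secondary siRNA median -1.38.

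The named PPR genes lie near each other on chromosome 1 and share reads, which were divided equally among their hits. AT1G62910 (23298948 to 23301141) was 10.6-fold lower (10.0 to 11.2), with 655 RPM in DDH, 61.9 in DAH and 81.9 in the vector library. AT1G63080 (23387574 to 23390838) was 9.50-fold lower, AT1G62914 (23301315 to 23303162) 7.66-fold, AT1G63400 (23507178 to 23509484) 7.49-fold and AT1G63130 (23412518 to 23415155) 5.53-fold. In each of these 5 genes the DAH level also lay under that of the vector library, at 0.755, 0.359, 0.532, 0.656 and 0.479 of it. The siRNA TGAGGGAGCTGTAGGTAAAAA, common to AT1G62910 and AT1G63080, had 10198 reads in DDH, 132 in DAH and 207 in the vector library. With uniquely placed reads alone the PPR median was -2.85 (-4.19 to -2.07) over 13 genes, and its percentile was not computed.

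The 7 other genes on the list, among them AGO1 and the auxin receptors, had a median of -1.53 (-1.83 to -1.07) at percentile 17.0 among matched lists. AFB3 was 3.55-fold lower (3.12 to 4.05), TIR1 3.14-fold (1.90 to 5.41) and AFB2 2.10-fold (1.61 to 2.73). Of 41 miRNA target genes not known to give such siRNAs, 19 could be measured. ARF2 and ARF4 are among the 19, and as auxin response factor genes they belong to the class that tasiARF regulates. All 19 were lower, 14 over 2-fold, with a median of -1.71 (-2.14 to -0.99) at percentile 0.04. With the median of other genes set to 0, 5 were over 2-fold lower and the median was -0.63. Examples are HAM3 at 12.6-fold (7.45 to 23.0) on 189 DDH reads and 15 DAH reads, and AP2, a floral identity gene, at 10.6-fold (6.24 to 19.4) with 7.71 RPM in DDH and 0.728 in DAH. AGO2 was 1.20-fold lower (0.942 to 1.55) and TCP4 1.23-fold (0.840 to 1.80), intervals that include 1.

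**Figure D4:**
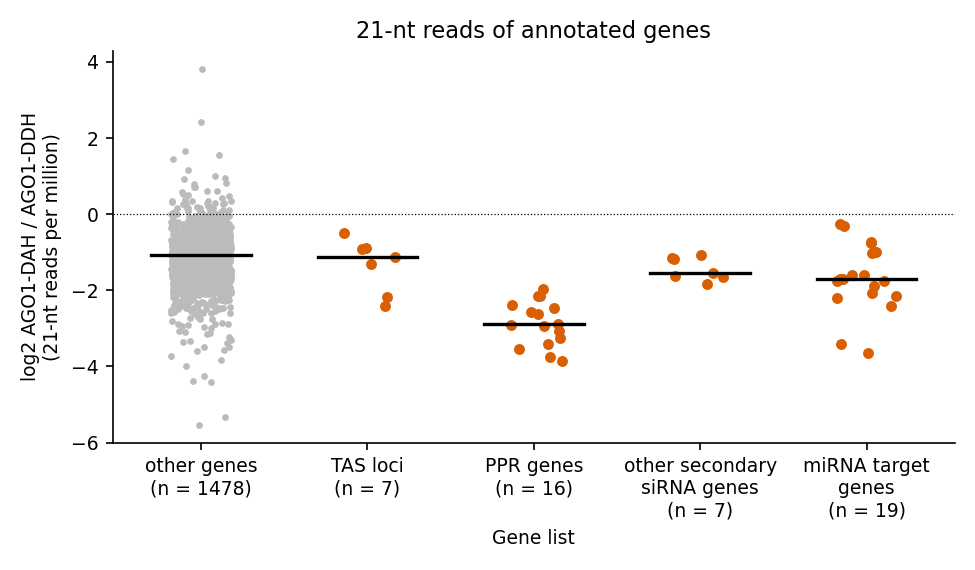
Log2 ratio of 21-nt RPM in AGO1-DAH over AGO1-DDH (vertical axis) for genes with at least 50 reads over both libraries, by gene list (horizontal axis), with 1 point per gene, a bar at the median and 1 library per group. The median is -1.09 over 1478 other genes, -1.13 for 7 TAS loci, -2.89 for 16 PPR genes, -1.53 for 7 other secondary siRNA genes and -1.71 for 19 miRNA target genes.

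At the AGO1 gene itself (AT1G48410, chromosome 1, 17885633 to 17892632, minus strand), which the tagged transgene copies and miR168 targets, 21-nt reads were 335 RPM (327 to 343) in DDH and 116 (111 to 121) in DAH, against 23.5 in the vector library. DDH stood 2.89-fold above DAH (2.76 to 3.03). Antisense reads, whose origin was not tested, were 180 RPM in DDH, 37.9 in DAH and 11.1 in the vector library, and sense reads 155, 77.9 and 12.5. The antisense siRNA TGTGTAGGACGAATGCTTTGG (chromosome 1, 17890533 to 17890553, plus strand) had 415 reads in DDH, 26 in DAH and 3 in the vector library. The sense siRNA TACACAGATGGGCTTATCACT (17890518 to 17890538) had 334 in DDH and 307 in DAH, a DAH over DDH ratio of 0.919 (0.784 to 1.08) whose interval includes 1. Reads of the transgene and of the native gene cannot be separated.

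Repeat-derived 24-nt siRNAs, a class known from the AGO4 group, served as a contrast class. In pseudogenes and masked repeats they made up 2.36% of DDH reads, 1.06% of DAH reads and 2.33% of vector reads. DDH stood 2.22-fold above DAH, a log2 ratio of -1.15 for DAH over DDH, and 1.01-fold above the vector library. The ratio ran from -1.38 scaled to miRNA family reads to -0.68 with full weight at every hit. These values count every first base and do not measure AGO4-like reads. Of all 24-nt reads, 96.96% in DDH and 85.9% in DAH began with U. The 24-nt reads with a 5′ A went the other way, with 1901 RPM in DDH, 3944 in DAH and 70478 in the vector library. A single 24-nt sequence, TCTGGTGTTGTAGAACTTATGATC of the pseudogene AT3G43832 (chromosome 3, 15682359 to 15682382, plus strand), had 92094 reads in DDH, 5468 in DAH and 10786 in the vector library. The whole class of pseudogenes and masked repeats had 486285, 219523 and 475590 in the same order. Its DDH to DAH ratio without that sequence was not computed.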

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

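The tests of reads shared between paralogs and of a few over-amplified sequences were set before their results were seen, and the tests of dilution, lost siRNA production, abundant in-register sequences, a 1-nt shift, shared TAS1 sequences, vector-like background, amplification of 1 miR168 sequence and star reads were chosen after the results, or parts of them, had been seen.

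For 4 miRNA families the DDH and DAH libraries lay on opposite sides of the vector library, a difference that was not tested, since each group had 1 library. The log2 ratio to the vector library was -0.10 in DDH and 2.21 in DAH for miR168, and 1.21 and -1.13 for miR390. It was -0.25 and 0.26 for miR394, and 1.51 and -0.64 for miR843. Under the median of family ratios all 4 lay below the vector library in both, at -2.46 and -0.0043 for miR168, -1.15 and -3.34 for miR390, -2.60 and -1.96 for miR394, and -0.85 and -2.86 for miR843. Several mature miRNAs outside the listed families also stood above the vector library in DDH, while miR8183 and miR869.2 stood at 0.768 and 0.414 of its level. The 6 most abundant outside the families in DDH, all above the vector library, were miR447a.2-3p at 26124.5 RPM, miR824-5p at 752, miR771 at 339, miR867 at 266, miR5026 at 245 and miR397b at 139.

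The 16 measured PPR genes were lower in DAH with a median log2 ratio of -2.89. Dilution by the larger miRNA share of DAH would lower all genes alike, and the PPR median lay -1.81 from that of the other genes, which argues against it as the whole cause. Reads shared between paralogs are argued against by a median of -2.85 over 13 genes with uniquely placed reads, and a few over-amplified sequences by -2.56 with the 3 most abundant of each gene left out. A biological hypothesis is that siRNA production after cleavage by the tagged AGO1 may be lost in the slicer mutant. Cleavage by native AGO1 in the DAH line was not measured, so these plants cannot be taken to lack AGO1 slicing. The other secondary siRNA genes stood at percentile 17.0 among matched lists, with a median of -1.53, which decides nothing. The 19 measured target genes not known to give secondary siRNAs, the contrast list, were lower too, with a median of -1.71 at percentile 0.04. A low percentile was therefore not particular to genes known to give such siRNAs. The TAS loci stood at percentile 74.2, with 3 of them outside the abundance range to match. Those cut with AGO7 were lower in DAH as well, 1.88-fold at TAS3a, 1.84-fold at TAS3b and 5.31-fold at TAS3c. The hypothesis cannot be told apart from a difference between these 2 libraries, because each genotype had 1.

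The share of reads in the miR173 register was lower in DAH at TAS1a, TAS1b, TAS1c and TAS2, by a median of -27.8 percentage points. Without the 3 most abundant sequences of each locus, whatever their register, a median of -20.9 points stayed. The difference was then -31.2 instead of -64.3 at TAS1a and -9.42 instead of -20.9 at TAS2, so those sequences carry part of it there. Whether abundant in-register sequences are the whole cause was not decided, because the sequences left out were not chosen by register. With each distinct sequence counted once the median difference was -1.25, so it was seen in read counts and hardly in the share of distinct sequences. The number of in-register kinds was not compared. Argued against are a shift by 1 nt (-29.2 with neighbouring registers counted) and sequences shared between the TAS1 loci (-23.7 with uniquely placed reads). The same holds for vector-like background at TAS1a and TAS1c, where the vector share lay at least 35.7 points above DAH. Such background is argued against at TAS1b and TAS2 too, since with the whole vector level taken off the register share of the other DAH reads minus that of DDH was -24.1 points or lower, and the slicer mutation stays open as an untested explanation, since library and genotype are confounded.

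miR168 had the highest ratio of DAH to DDH among families with at least 1000 reads. Amplification of 1 sequence is argued against because 14 of 14 miR168 sequences with 20 or more reads (100%) were over 2-fold higher in DAH, and unsorted duplexes because the star reads had a log2 ratio of -0.76. The slicer mutation stays open as an untested explanation, since library and genotype are confounded.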

How the results depend on the processing

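The scalings to reads outside miR159 and to the median of other genes, leaving out the 3 most abundant sequences, and the other TAS3 site were chosen after seeing the data. For the PPR genes, the test without those sequences was set before its own result was seen. No paired analysis was possible because each group had 1 library. In each list below the cause was not tested unless the setting itself gives it. The summary values moved in 67 cases, reversed in 2 and held in 152. Values of single named families and genes moved in 483, reversed in 16 and held in 332, where only a value over 2-fold counts as reversed when its sign turns, and a smaller one counts as moved or held. Counting intervals are narrow at this depth, so small moves count. No alternative gave another direction for the TAS, PPR, secondary siRNA or target gene medians or for the miR173 registers.

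With each distinct sequence counted once, the 21-nt share was 10.6% in vector, 23.5% in DDH and 20.1% in DAH, and the 5′ U share 40.3%, 80.4% and 76.4%. Without structural and organelle reads the 21-nt shares were 80.4%, 65.7% and 72.7%. Without miRNA reads the 5′ U shares were 35.5%, 87.3% and 82.5%. In both of these 5′ U settings DDH lay above DAH, the reverse of the main values. The miRNA precursor share in vector, DDH and DAH was 83.8%, 74.6% and 85.7% with uniquely placed reads, 57.3%, 54.8% and 70.7% with full weight at every hit, and 80.7%, 74.5% and 85.3% for 20 to 24 nt. The TAS share was 0.435%, 1.81% and 1.21%, then 0.252%, 0.806% and 0.517%, and 0.394%, 1.47% and 0.923% under the same settings.

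Under the median of ratios over families, which sets the family median near 0 by construction, the median log2 ratio to vector reversed to -0.15 in DDH and -0.067 in DAH. Then 14 and 11 families were over 2-fold higher and 16 and 14 lower. Among values over 2-fold, in DDH it reversed miR160 (-0.59), miR166 (-0.65), miR390 (-1.15), miR395 (-0.15), miR396 (-0.017), miR472 (-0.15), miR843 (-0.85) and miR848 (-0.52). In DAH it reversed miR160 (-0.070), miR164 (-0.79), miR166 (-0.38), miR167 (-0.80), miR168 (-0.0043), miR408 (-0.18) and miR840 (-0.27). Smaller values turned too, in DDH for miR161 (-2.32), miR162 (-1.39) and miR164 (-1.88), and in DAH for miR161 (-2.13) and miR162 (-1.80). With the exact guide only, miR840 in DAH over vector reversed to -0.53, and DAH over DDH turned to 1.05 for miR319 and -0.30 for miR447. Scaled to reads outside miR159, the DDH median over vector was 1.15, with 9 families over 2-fold lower in DDH and 8 in DAH. With a minimum of 1000 reads, which leaves fewer families, 23 were higher and 2 lower in DDH.

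For DAH over DDH, reads outside miR159 as the base gave a family median of 0.24, with 9 families over 2-fold higher and 7 lower, and 2 TAS loci over 2-fold lower. Families over 2-fold higher were 3 when scaled to miRNA family reads and 3 with a minimum of 1000 reads, and 9 passed a fold limit of 1.5. With the median of other genes set to 0, the medians were -0.041 for TAS, -1.38 for secondary siRNA genes, -1.81 for PPR genes and -0.63 for target genes, with 2, 15 and 5 over 2-fold lower in TAS, secondary and target genes, and TAS1c (0.58), TAS3a (0.17) and TAS3b (0.21) turned. With all lengths 2 TAS loci were over 2-fold lower. Target genes over 2-fold lower were 22 with a minimum of 10 reads, where more genes enter, and 9 without the 3 most abundant sequences.

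The median difference in miR173 register share was -1.25 with each distinct sequence once. With all precursor reads outside the guide as star, the median difference was 0.194 points and 22 families had a higher share in DAH. With uniquely placed reads 8 were higher and 7 lower, among 16 families. The 24-nt repeat ratio was -1.38 scaled to miRNA family reads, -1.34 with uniquely placed reads and -0.68 with full weight. At AGO1, reads of all lengths were 36.002 RPM in vector, 424 in DDH and 156.7 in DAH. Depth limits TAS4, whose few reads allow no direction, and miR828, which rests on 6 reads.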

Other observations

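The items here were picked after their values were seen. Outside the gene lists, the pseudogene AT3G23645 (chromosome 3, 8509762 to 8510165, minus strand) had 15.9-fold fewer 21-nt reads in DAH, with 175 against 2779 in DDH and 363 in the vector library. The pseudogene AT1G42630 (chromosome 1, 16025298 to 16025762, plus strand) went the other way, 14.2-fold higher with 754 reads in DAH, 53.2 in DDH and 26 in the vector library. Of the 1478 other genes, 6 were over 2-fold higher in DAH and 826 over 2-fold lower. AT1G12300 and AT1G12775 on chromosome 1, which were not on the lists, were 9.42-fold and 8.85-fold lower. TPS2 (AT1G16980), a trehalose-phosphate synthase gene, was 10.5-fold lower.

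Forms of some miRNAs differed in length between the libraries. Of miR161 reads, 55.3% were 20 nt long in DDH, 35.5% in DAH and 7.24% in the vector library. Of miR319 reads, 29.8%, 42.0% and 31.3% were 20 nt. The 22-nt sequence TTTCATCTGTAGAACAAGAAAG within AT2G06555 (chromosome 2, 2604648 to 2604669, minus strand) had 27364 reads in DDH, 11517 in DAH and 42 in the vector library. Among annotated miRNAs outside the listed families, miR4228-3p was 2.48-fold higher in DAH and miR780.2 was 4.97-fold lower.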
